A study of Bacillus subtilis with 6 samples.

How the data were processed

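Total RNA from 6 samples of Bacillus subtilis NCIB 3610 was measured by RNA sequencing, with 3 libraries exposed to DMSO and 3 to AQCA. Per the labels, RNA was extracted with an OMEGA Total RNA kit and libraries were made with the NEBNext Ultra II Directional kit, which keeps the strand. Per the submitters' processing notes, the tools were Bowtie2, HTSeq 0.6.1 and RSEM, with no role or order stated; the genome build, the annotation and the number of reads are not given in the sources used here. The values are FPKM, fragments per kilobase scaled for library size, which the authors deposited as a table per library with the same 4279 genes in the same order. No counts were used here, so no count model was fitted. The labels place all libraries in batch 1, name the cell type as biofilm and planktonic bacteria together, and number the AQCA libraries 1 to 3 in the titles but 4 to 6 in the descriptions; the title numbers are used here. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

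Groups came from the sample titles. DMSO replicate 1 was left out of the tests because its label describes it as abnormal and not used downstream, which left 2 DMSO and 3 AQCA libraries. Genes with at least 1 FPKM in at least 2 of these 5 libraries were tested, 4036 in all, and 243 were not. FPKM values were used as deposited, with no further scaling, as log2(FPKM + 1). AQCA was compared with DMSO by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with 3 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the FPKM + 1 scale and understate the change of low genes. A gene listed at 0 throughout a group is given with the value of each library and no fold. The tests, the libraries in them, the alternatives and the rule for single genes were fixed before the data were examined.

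The fit was tested on simulated data with the spread of these libraries, 2 DMSO against 3 AQCA libraries, in 5 simulations of 200 changed genes each and on average 4053.8 genes tested. It recovered 46.2% of 2-fold changes and 86.0% of 4-fold changes, and 3.50% of the calls were false. Many changes of about 2-fold were therefore missed in these simulations. The changed genes were all at 10 FPKM or more in the 5 libraries, and no scaling difference was put between the groups. In the data 27.5% of the tested genes were called, a far larger share than was changed in the simulations. The simulated rates of recovery and of false calls therefore do not carry over to the calls below.

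Gene names could not be attached. The identifiers in the tables were looked up in a reference table of 4536 genes, and 0 matched, so 44 gene lists fixed beforehand (matrix, motility, sporulation, stress and metabolic genes among them), the set tests on them, and 6 genes that were always to be given (tasA, epsA, hag, sinR, slrR and spo0A) were not analysed here. The rule for single genes took, among called genes with a mean of at least 10 FPKM in a group and with the groups fully separated, the 12 with the largest rise and the 12 with the largest fall; because identifiers cannot be read as gene names, 2 in each direction are printed and the rest are summarised. Runs of neighbouring genes, meaning at least 5 consecutive tested genes in identifier order called in the same direction, were chosen as a description after the lack of names was seen. The tables list genes in increasing order of identifier number; whether this is the order along the chromosome is not given in the sources used here. Runs were compared with 9999 shuffles of the calls over the tested genes. The shuffles treat calls as independent, so neighbours that vary together for any reason would exceed them.

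Depth was read from the values. A set of 14 genes had values that are whole multiples of a step shared within a library, as genes of the same, very small effective length would have, and the step was taken as 1 read in such a gene. It was 1630.41 and 1783.17 FPKM in DMSO replicates 2 and 3, 1364.51, 1825.16 and 1659.08 FPKM in AQCA replicates 1, 2 and 3, and 1619.91 FPKM in DMSO replicate 1. The rule for finding the step was changed after an earlier version gave values that were double or a simple fraction of these in 2 libraries. The resulting depth ratios were compared with those from genes of low FPKM, and differed by at most 0.03 on the log2 scale in all 10 pairs of the 5 tested libraries but in only 1 of 5 pairs with DMSO replicate 1, whose step is therefore uncertain. The largest step was 1.34 times the smallest. Of the 14 genes, 12 had a value above 0 in any of the 5 tested libraries. Absolute depth stayed unknown, since the effective length behind the step is unknown, and no interval or detection limit was computed from it. FPKM of the 14 genes is not a measure of abundance comparable with other genes: the highest such value, 143476 FPKM, stands for 88 steps. Of the 4279 genes, 372 were listed at 0 in some but not all of the 5 libraries, and among the 1110 calls 19 involved a value of 0 and 10 a group listed at 0 throughout.

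The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 10 FPKM, median-of-ratios scaling, quantile normalization, rescaling to a total of 1000000, eBayes without a trend or with robust estimation, DMSO replicate 1 included with and without limma array weights, the replicate number as a block, each library left out in turn, and a minimum fold of 2. After the data were seen, a fit without genes listed at 0 in any of the 5 libraries was added, and the runs were recounted under the alternatives. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading the tables, the depth estimates and the plots.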

Results

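RNA was sequenced from wild-type Bacillus subtilis NCIB 3610, a strain that forms robust biofilms on the minimal medium MSgg. Biofilms were grown for 48 h and then exposed for 24 h either to the solvent DMSO or to the compound AQCA at 25 µg/mL. There were 3 libraries per group, numbered replicates 1 to 3, and the labels set DMSO replicate 1 aside as abnormal, so that 2 DMSO libraries and 3 AQCA libraries entered the tests. Each library gave an FPKM value for the same 4279 genes. Total FPKM was 4000457 and 3780507 in DMSO replicates 2 and 3, and 2397996, 2723755 and 3031672 in AQCA replicates 1, 2 and 3. Between 165 and 285 genes were listed at 0 in these 5 libraries. Total read counts were not given in the sources used here, but repeated steps in the values put the most deeply and the least deeply sequenced of the 5 tested libraries within a factor of 1.34 of each other. The gene identifiers carried no gene names and none matched the reference gene table, so genes are described by their place in the identifier order, by groups of neighbours, and by 2 identifiers in each direction.

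The comparison of AQCA with DMSO asks which transcripts differ when the compound is added to cultures with a mature biofilm. The labels describe the cells as biofilm and planktonic bacteria together, and their shares were not measured here, so no change can be assigned to either. Expression shifted broadly, with 643 genes higher and 467 lower among 4036 tested, which together made up 27.5% of the tested genes. Among the genes called with the deposited values, falls were larger than rises. The median log2 fold change was 0.94 among the higher genes and -1.54 among the lower ones. At least 4-fold changes were seen in 161 genes that fell and 52 that rose. Some of these fitted changes belong to the 10 called genes listed at 0 throughout a group; without them, 156 genes fell and 48 rose at least 4-fold. Of the remaining genes, 21 rose at least 16-fold, all within a block of neighbouring genes, and 0 fell as much. In every called gene, all 3 AQCA libraries lay on the same side of both DMSO libraries. Such separation occurred in 2303 tested genes, or 57.1%, where chance gives 20% for a single gene. All genes share the same libraries, so any difference between whole libraries moves many of them at once. The share therefore does not measure the extent of an effect of AQCA.

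Calls were made with limma on log2(FPKM + 1), two-sided, at a Benjamini-Hochberg adjusted p under 0.05. The number of higher genes varied with the libraries fitted. It was 598 without AQCA replicate 1, 214 without AQCA replicate 2 and 356 without AQCA replicate 3. The number of lower genes was 458, 297 and 385 in the same order. Without DMSO replicate 2 or 3, which leaves 1 DMSO library, the median log2 fold change of all tested genes was 0.25 or 0.09. No called gene that could be tested changed sign in any of these fits, but this outcome was fixed in advance. In every called gene all AQCA libraries lay on the same side of both DMSO libraries. Leaving out 1 library could therefore not reverse the sign. Each of these fits had fewer libraries, so a change from the main fit cannot be assigned to the library left out alone. The 3 fits without an AQCA library were of equal size, so the differences between them go with the library left out. AQCA replicates 2 and 3 were the closest AQCA pair, with a median absolute log2 difference of 0.18 against 0.305 and 0.344. Whether this accounts for the counts was not tested. The balance of directions rested on the scaling, because the median log2 fold change of all tested genes was 0.18 with the deposited values, 0.02 after median-of-ratios scaling and 0.61 after rescaling every library to a total of 1000000. Higher genes were 57.9% of the calls with the deposited values, 40.9% (378 higher, 547 lower) after median-of-ratios scaling and 84.0% (1598 higher, 305 lower) after the rescaling. That rescaling leans on a single gene, described below, which held 47.3% and 45.9% of total FPKM with DMSO and 29.2% to 40.2% with AQCA. A lower share of this gene leaves a larger share to all other genes together. The excess of 4-fold falls over 4-fold rises was present after median-of-ratios scaling, with 197 genes lower and 45 higher. It was absent after the rescaling, with 76 lower and 78 higher. The median change of the called genes was then still larger for falls (-1.51) than for rises (1.10). The rescaling also changed which genes were called in each direction, so these medians do not show that falls stayed larger.

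**Figure D1:**
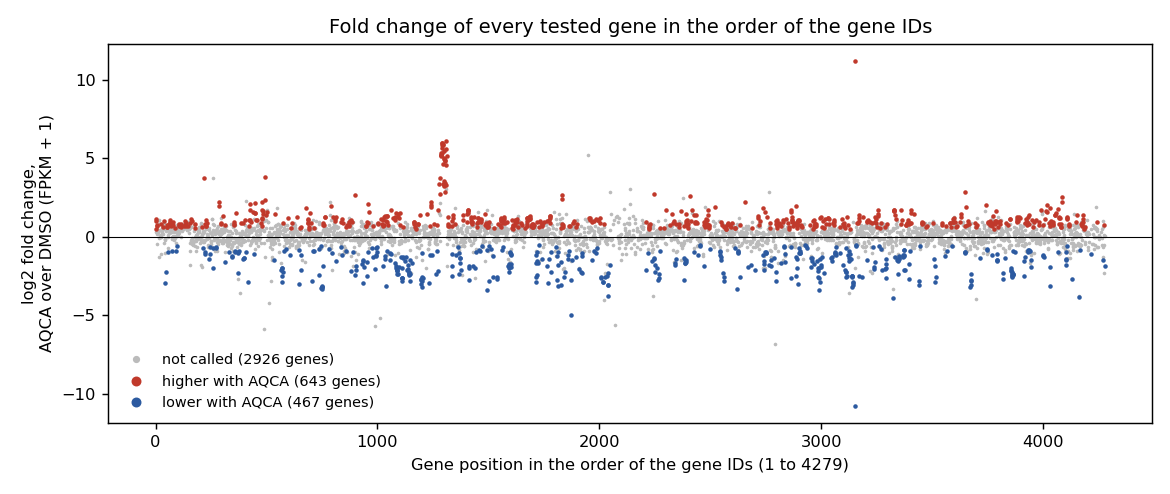
Log2 fold change of AQCA over DMSO, on FPKM + 1, for each of the 4036 tested genes (vertical axis) against the place of the gene in the identifier order (horizontal axis). Red points are the 643 higher genes, blue points the 467 lower genes and grey points genes not called. The tall red column is the block at positions 1285 to 1312. The 2 most extreme points, at positions 3151 and 3152, rest on a few steps, each taken as 1 read.

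The strongest rise was a block of neighbouring genes. From position 1285 to 1312 in the identifier order, 27 of 28 genes were higher with AQCA, by 2.87 to 6.10 on the log2 scale with a median of 5.14, a 35.4-fold rise. Among the 27, the gene at position 1305 was listed at 0 in DMSO replicates 2 and 3, and without it the median was 5.18. The remaining gene, at position 1308, was not called (limma adjusted p = 0.167) and divides the block into a run of 23 genes and a run of 4. In the run of 23, the median over genes went from 3.50 FPKM with DMSO to 165 FPKM with AQCA, that is, from below the medians of the tested libraries, 50.01 to 56.16 FPKM, to above them. The edge at position 1285 comes from the rule of consecutive calls: of the 6 genes before it, those at positions 1279, 1280 and 1282 were also higher, by 3.34, 3.74 and 2.72 on the log2 scale, and the other 3 were not called. The median log2 fold change of the run of 23 was 5.12 ± 0.62 (SD over AQCA libraries, n = 3). Because these genes are low with DMSO, the size depends on the pseudocount, and the median was 4.34 with a pseudocount of 5 and 5.44 with 0.1. Each library taken alone showed the same contrast: the median over the 23 genes was 3.62 and 3.68 FPKM in DMSO replicates 2 and 3, and 237, 120 and 137 FPKM in AQCA replicates 1, 2 and 3. DMSO replicate 1, which was not tested, had a median of 6.38 FPKM in the run.

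**Figure D2:**
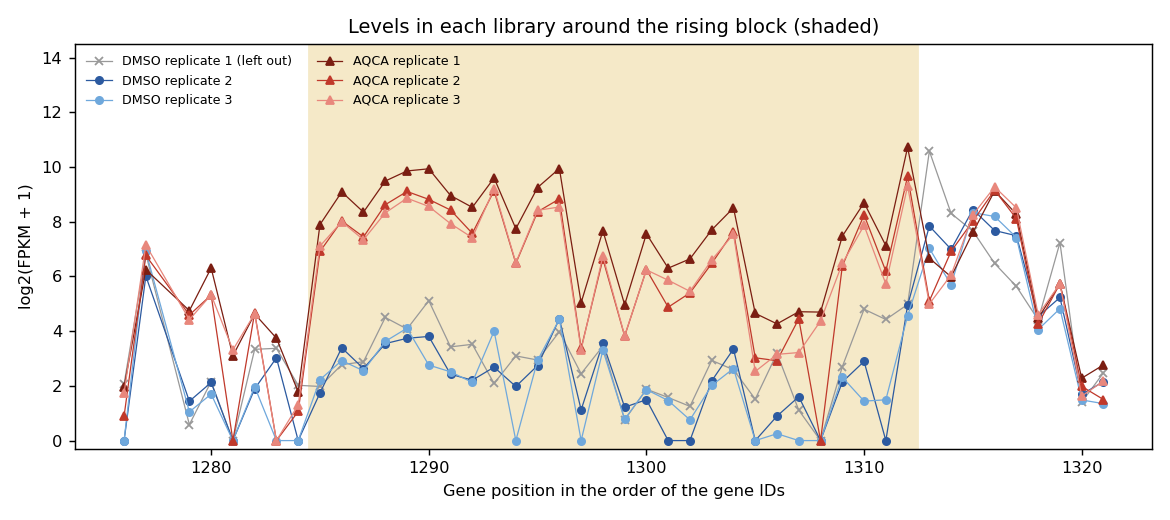
Expression as log2(FPKM + 1) in each of the 6 libraries (vertical axis) for tested genes around the rising block, by place in the identifier order (horizontal axis). Lines join the genes of a library; in the shaded block, positions 1285 to 1312, the 3 AQCA libraries (triangles) lie above DMSO replicates 2 and 3 (circles) at every gene but position 1308, and DMSO replicate 1 (crosses), which was left out of the tests, runs near the other DMSO libraries over most of the block.

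Other higher genes also sat next to each other. Counting runs of at least 5 consecutive tested genes called in the same direction, 11 runs with 88 genes were higher, which is 13.7% of all higher genes. After the block, the next longest was a run of 17 genes at positions 1672 to 1688, with a median log2 fold change of 1.17 ± 0.24 (SD over AQCA libraries, n = 3) and median levels of 44.4 FPKM with DMSO and 105 FPKM with AQCA. The other 9 higher runs held 5 or 6 genes each and had median log2 fold changes between 0.72 and 1.68. With the calls shuffled over the tested genes, 1.80 genes on average and at most 22 fell into such runs (permutation test, p = 1e-04, the smallest that 9999 shuffles can give). The number of higher runs was 2 without DMSO replicate 2, 3 without DMSO replicate 3, and 4 without AQCA replicate 2 or without AQCA replicate 3. It was 4 after median-of-ratios scaling and 71 after rescaling to 1000000.

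Lower genes also sat next to each other, and their runs showed larger changes than most of the higher runs. A total of 13 runs with 88 genes were lower, which is 18.8% of all lower genes, and in 9 of the 13 runs the median fall was at least 4-fold, against 1 of the 11 higher runs with a rise of that size. The longest was a run of 12 genes at positions 3855 to 3866, where the median level went from 970 to 197 FPKM (median log2 fold change -2.37 ± 0.20, SD over AQCA libraries, n = 3). A run of 9 genes at positions 3136 to 3144 went from 631 to 83.8 FPKM (-2.56 ± 0.39). The deepest fall of a run was that of 5 genes at positions 748 to 752, from 996 to 110 FPKM (-3.21 ± 0.20), which is 9.28-fold lower. A run of 6 genes at positions 1196 to 1201 had the highest FPKM of the lower runs, at 21500 FPKM with DMSO and 2776 FPKM with AQCA (-2.77 ± 0.26). A further 5 lower runs with median falls of at least 4-fold held 6 genes at positions 1108 to 1113 (-2.59), 5 genes at positions 3672 to 3676 (-2.78), 8 genes at positions 1139 to 1146 (-2.26), 5 genes at positions 3111 to 3115 (-2.26) and 6 genes at positions 1085 to 1090 (-2.11).

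Shuffled calls put 0.375 lower genes on average and at most 12 into such runs (permutation test, p = 1e-04, again the smallest that 9999 shuffles can give). The number of lower runs was between 9 and 13 with any 1 of the 5 libraries left out, 14 after median-of-ratios scaling and 8 after rescaling to 1000000. After this rescaling, 5 of the 13 lower and 2 of the 11 higher runs had a median change of at least 4-fold. Across both directions, 7 of the 24 runs (3 higher, 4 lower) kept every gene called under all 3 other scalings, quantile normalization included.

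Among single genes with a mean of at least 10 FPKM in a group, the 12 largest rises included 11 genes of the block. The largest of these was gene-EJJ34_RS07125, which rose from 6.44 and 1.72 FPKM in DMSO replicates 2 and 3 to 413, 304 and 232 FPKM in AQCA replicates 1, 2 and 3. Its log2 fold change was 6.10 with a standard error of 0.46 (limma adjusted p = 0.000859), a 68.6-fold rise on the FPKM + 1 scale. The size of this rise rested on the pseudocount and on the DMSO libraries, with a log2 fold change of 5.16 with a pseudocount of 5, 6.48 with a pseudocount of 0.1, 6.83 without DMSO replicate 2, 5.37 without DMSO replicate 3 and 5.22 with DMSO replicate 1 included, where the gene was at 26.9 FPKM. Of the 12 largest falls, 3 genes were listed at 0 in every AQCA library, and the other 9 fell between 9.19-fold and 14.8-fold. One of the former was gene-EJJ34_RS10000, at 29.1 and 31.1 FPKM in DMSO replicates 2 and 3 and listed at 0 in AQCA replicates 1, 2 and 3 (limma adjusted p = 0.000681). Of the 12 largest falls, 4 belonged to the lower runs.

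The most extreme fitted changes rested on very few steps, where a step was taken as 1 read. The gene with the largest fitted rise, gene-EJJ34_RS16890, was listed at 0 in both DMSO libraries and at 1365, 1825 and 4977 FPKM in AQCA replicates 1, 2 and 3 (limma adjusted p = 0.00039). These values equal 1, 1 and 3 times the step of the library, and 8, 8 and 7 genes lay at multiples of that step. The gene with the largest fitted fall, gene-EJJ34_RS16850, was at 1630 and 1783 FPKM in DMSO replicates 2 and 3, which is 1 step in each, and listed at 0 in the AQCA libraries (limma adjusted p = 8.98e-06). Read as whole reads, these are 5 reads with AQCA and 0 with DMSO for the rising gene, and 2 reads with DMSO and 0 with AQCA for the falling gene. With DMSO replicate 1 included, gene-EJJ34_RS16850 was no longer called (limma adjusted p = 0.162).

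The gene with the highest value was the same in all 6 libraries and took a large part of the total. It held 47.3% and 45.9% of total FPKM in DMSO replicates 2 and 3, and 29.2%, 37.0% and 40.2% in AQCA replicates 1, 2 and 3. In DMSO replicate 1, which was not tested, it held 31.5% of the total, a share within the range of the AQCA libraries. Its mean was 1813670 ± 108765 FPKM with DMSO (SD, n = 2) and 976005 ± 260406 FPKM with AQCA (SD, n = 3). All 3 AQCA libraries, at 700977, 1008251 and 1218786 FPKM, lay below both tested DMSO libraries, at 1890578 and 1736761 FPKM. DMSO replicate 1 was at 1275264 FPKM. The log2 fold change of -0.93 was not called (limma adjusted p = 0.424). Its standard error of 0.79 combines the spread of this gene with a trend over genes by level. The missing call is therefore not evidence that the level was unchanged.

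The library that the labels call abnormal, DMSO replicate 1, was compared with the other 5. Its profile was the least like any other: across the 4279 genes, Pearson's r of log2(FPKM + 1) was 0.820 with DMSO replicate 2, 0.812 with DMSO replicate 3 and between 0.736 and 0.765 with the AQCA libraries. The other libraries were far closer, with r = 0.961 between DMSO replicates 2 and 3, 0.955 to 0.971 between AQCA libraries, and 0.902 to 0.937 between those DMSO libraries and the AQCA libraries. These correlations are across genes, which are not independent replicates, and with 1 library no test was made. The median absolute log2 difference of DMSO replicate 1 from DMSO replicates 2 and 3 was 0.82 and 0.91, against 0.29 between the latter. From the AQCA libraries it was 1.04 to 1.08, against 0.49 to 0.66 for DMSO replicates 2 and 3. DMSO replicate 1 listed 113 genes at 0, fewer than any other library. Its median was 83.0 FPKM where the others lay between 50.01 and 56.16 FPKM.

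The genes called between AQCA and the 2 other DMSO libraries mostly sat on the DMSO side in DMSO replicate 1. Of the 643 higher genes, 482 (75.0%) were below every AQCA library there, against 30.3% of genes not called. Of the 467 lower genes, 436 (93.4%) were above every AQCA library, against 53.2% of genes not called. When DMSO replicate 1 was added to the test, 194 genes were higher and 278 lower, so that higher genes were 41.1% of the calls.

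**Figure D3:**
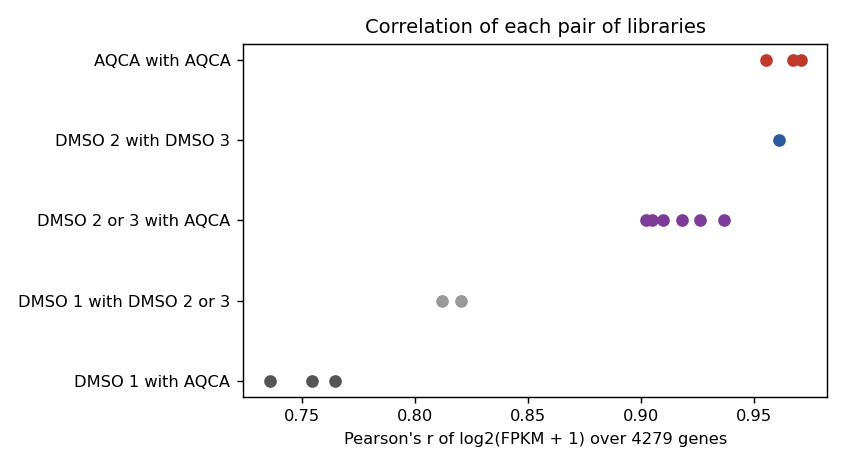
Pearson's r of log2(FPKM + 1) over the 4279 genes (horizontal axis) for each pair of the 6 libraries, with 1 point per pair and pairs grouped by kind (vertical axis). Pairs with DMSO replicate 1 lie between 0.736 and 0.820, and all other pairs at 0.902 or above.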

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

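The tests that weigh explanations for DMSO replicate 1 and for the block, and both tests with shuffles, were chosen after the results were seen; the correlations between libraries and the limma calls were planned.

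DMSO replicate 1, left out of the tests, held a large signal of its own. In this library 440 genes with at least 10 FPKM were more than 4-fold above every other library, where each of the other 5 libraries had 1 to 5 such genes, and 27 genes were more than 4-fold below every other library, where the others had 1 to 7. The 440 genes were not spread evenly: 70 pairs of them were neighbours in identifier order, against a mean of 45.1 in shuffled orders (permutation test, p = 2e-04, 9999 shuffles). Of the 380 that were tested between AQCA and the other DMSO libraries, 50 (13.2%) were called lower with AQCA and 14 (3.68%) higher, against 11.6% lower and 15.9% higher among all tested genes.

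Several technical explanations for DMSO replicate 1 were weighed. An AQCA library under a DMSO label is argued against by the correlations, since its lowest r with a DMSO library exceeded its highest with an AQCA library by 0.0475, and by its median of 6.38 FPKM in the block of 23 genes that stood at 120 to 237 FPKM in the AQCA libraries. A shallower library is neither shown nor excluded by its 113 genes listed at 0, fewer than the 165 to 285 of the other libraries. Zeros depend on which genes are present as well as on depth, and the step of this library was uncertain. An even background over all genes, as DNA would give, is argued against as the source of most of the excess: the 440 genes exceeded the highest other library by a median of 154 FPKM, and 63.7% of all genes in the library lay below that level, where such a background would hold them above it. Depth, RNA quality, a culture at another stage and an outside sample stay open. No biological explanation was tested because the labels give this library no condition of its own.

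The block of 27 rising genes at positions 1285 to 1312 was examined through its run of 23. Scaling is argued against as its cause, because the median log2 fold change stayed at 4.96 or above under 3 other scalings, and so is a single library, because it stayed at 4.80 or above with any of the 5 libraries left out. A chance order of independent calls is argued against by the shuffles, in which the longest run had 9 genes (permutation test, p = 0.0001, the smallest that 9999 shuffles can give). Neighbours that vary together for any reason would give the same outcome, so the shuffles say nothing about the cause. That genes adjacent in identifier order were switched on together in the cultures exposed to AQCA remains a hypothesis, found on these libraries and not tested here. What the genes encode and whether the rise lies in biofilm or planktonic cells stays open. The labels do not say that replicates were separate cultures, so a difference between cultures apart from AQCA was not tested.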

How the results depend on the processing

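The added fit without genes listed at 0, the recount of runs and the reading of the block under the alternatives were chosen after the data were seen. No named gene changed direction; among the 1110 called genes, 22 changed sign with DMSO replicate 1 included and 2 after rescaling to a total of 1000000. Against 643 higher and 467 lower genes, median-of-ratios scaling gave 378 higher, rescaling to a total of 1000000 gave 1598 higher and 305 lower, and a minimum of 2-fold left 280 higher. With DMSO replicate 1 included the counts were 194 and 278, and with array weights, where that library had a weight of 0.0773 and the weights did not converge fully, 1032 and 743. Leaving out 1 library gave 200 to 598 higher and 246 to 458 lower genes; without a DMSO library the remaining one is assumed to vary like the AQCA libraries. The smaller number of libraries is part of each of these designs, and the cause was otherwise not tested. The replicate block gave 573 higher and 456 lower genes with the 5 libraries, and 45 and 119 with DMSO replicate 1 included. In the former fit AQCA replicate 1 had no DMSO library of the same number. Its block term absorbed it, so the fold changes came from the other 4 libraries, with 1 residual degree of freedom. Deviations of samples with the same number correlated at 0.04, -0.13 and 0.09, with the outlying DMSO replicate 1 part of the DMSO mean. With 4 libraries, replicates 2 and 3 of each group, the value for replicate 2 was -0.05. These few values show no pairing by number but cannot exclude it. All other alternatives, the added fit included (674 and 494), stayed within 1.5 times of both counts. Of the 1110 calls, 845 were kept under median-of-ratios scaling and 984 under quantile normalization. With DMSO replicate 1 included 472 were kept, and 163 with the replicate block as well. Without AQCA replicate 1, 2 or 3, the calls kept were 956, 502 and 704. For the 4 genes named, 67 of 69 alternative values kept their call, with no value for the falling genes when a DMSO library was left out; the exceptions were gene-EJJ34_RS16850 with DMSO replicate 1 included, without (adjusted p = 0.162) and with (adjusted p = 0.174) the replicate block. Over the alternatives, higher runs numbered 2 to 71, lower runs 3 to 25, and the median log2 fold change of the run of 23 lay between 4.34 with a pseudocount of 5 and 5.44 with 0.1. Set tests on gene lists were not run under any alternative, as no identifier matched a name. What depth limits was not measured, since the absolute depth is unknown.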

Other observations

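The exact binomial tests on reads, the counts over other splits of the libraries and the correlations of differences between libraries were chosen after the results were seen; the limma fits with and without DMSO replicate 1 were planned.

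The genes with the largest fitted rise and fall, gene-EJJ34_RS16890 and gene-EJJ34_RS16850, are neighbours among the listed genes, at positions 3152 and 3151, and change in opposite directions. Both belong to the 14 genes whose values are whole multiples of a shared step, and in the 5 tested libraries they held 5 and 2 steps in total. Whether counting error in a few reads accounts for the calls stays open. With AQCA holding 61.6% of the depth, 5 reads against 0 gave p = 0.164 and 2 against 0 gave p = 0.147 (exact binomial test, two-sided, counting error only), but these are the smallest p-values that so few reads can give in those directions, so the test could not have passed and decides nothing. Their adjusted p-values in limma, 0.00039 and 8.98e-06, come from log values in which 1 step and no step lie over 10 apart on the log2 scale.

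Other splits of the same libraries called few genes. Among the 10 ways to divide the 5 libraries into 2 and 3, the split by treatment called 1110 genes and was the only 1 to reach that number, and the highest of the others called 4. With DMSO replicate 1 included, the split by treatment called 472 genes, again the only 1 of 10 at that number, and the highest of the others called 1. In both designs 10 splits are too few to give a share under 0.05. Every other split also put DMSO and AQCA libraries together on at least 1 side. A difference between the groups, whatever its cause, then widens the spread within a side and lowers the calls. The low counts are therefore not a rate of false calls.

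Differences of DMSO replicate 1 from the other DMSO libraries showed at most a weak correlation, in the opposite direction, with those of AQCA. Across the 4036 tested genes, the difference of DMSO replicate 1 from DMSO replicate 2 correlated at -0.01 with that of AQCA from DMSO replicate 3. Its difference from DMSO replicate 3 correlated at -0.11 with the difference of AQCA from DMSO replicate 2. No spread was computed for these values, so a small relation is not excluded. Of all 1110 called genes, 74.2% were nearer in DMSO replicate 1 to the mean of the other DMSO libraries than to the mean of the AQCA libraries.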
